A study of Mus musculus with 16 samples.

How the data were processed

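Gene expression was measured in lung RNA of female C57BL/6N mice of 17 weeks on Illumina mouse BeadChips, single-colour arrays on which beads carry gene-specific probes. The labels place 16 arrays in 4 groups of 4, untreated wild type, untreated mutant, challenged wild type and challenged mutant, each array from a separate mouse. The mutant line is a knockout of Cox4-2, the gene named Cox4i2 on the array. Per the labels' protocols, challenged mice received 10 µg ovalbumin in 2 mg alum by intraperitoneal injection and were later exposed 3 times for 30 min to an aerosol of 1% ovalbumin. The labels give no treatment for the untreated mice, and do not say whether they were sensitised.

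Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns and checked by gel electrophoresis, and biotin-labelled cRNA was made with an Ambion MessageAmp kit. GenomeStudio 2011.1 is named in the submitters' processing notes, without its role. The deposited values used here are linear intensities. From the values, the authors' table is background subtracted, since about 23.5% to 23.8% of the values of each array lie below 0, and quantile normalised, since every array has the same upper quartile of 220.674 and the same highest value of 48649.2. The steps themselves are not given in the sources used here. The array medians lie between 27.8 and 28.0. A table of non-normalised signals and detection p-values, with 16 signal and 16 detection p columns, was not used here, because its column names match no sample label. Its probe symbols were looked at for probes without a name elsewhere. No slide or scan date is given in the sources used here, so no batch was tested.

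The design fixed beforehand used detection p-values and negative controls for the background. The deposited intensities carry neither, and hold negative values that have no logarithm, so a different course was taken. A normal-exponential background model (limma's normexp) was fitted to the deposited intensities with an offset of 16, and log2 values were taken without further normalisation. Fold changes of dim probes are therefore understated. The SD of the background noise was 10.2, and a probe counted as above background over an intensity of 16.8, the percentile 95 of that noise. A probe was kept when above background on at least 4 of the 16 arrays, which 15869 of 25697 probes were. Gene symbols came from the platform annotation, with 23978 probes carrying 1 symbol, 0 several and 1719 none. A reference gene table matched 23962 probes and changed 0 symbols. For a gene with several detected probes, the probe with the highest mean log2 intensity was tested, which left 11962 genes or unnamed probes, 11014 with a symbol and 948 without. In 2837 genes more than 1 probe was detected.

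Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with 1 coefficient per group over all 16 arrays, so that all groups shared 1 estimate of the spread (12 residual and 4.75 prior degrees of freedom). The contrasts were challenge within each genotype, genotype within each treatment, and the interaction, the difference between the 2 challenge responses. P-values were adjusted by Benjamini-Hochberg over all 11962 features, with a threshold of 0.05. A gene not above background on any array of a group has only a bound there, and its change is given as at least a fold, the brighter group's mean against the background limit or the dim signal, whichever was higher. Exact permutation tests over 4 against 4 arrays were 2-sided and can give no p below 0.0286.

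Before the data were examined, 37 gene lists were fixed, covering pathways, cell types of the lung and markers of other tissues that a lung sample could hold. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 37 lists within a contrast, and again with a correlation estimated per list and with fry, which asks whether a list's genes move on balance in 1 direction. Camera compares a list with the other genes. A list score is the mean log2 value of its members on an array, relative to the mean of the untreated wild type. The named genes were also fixed by rule: Cox4i2, up to 8 rises and 8 falls of largest size among genes past the threshold whose groups did not overlap, the 10 genes of smallest p where fewer than 5 genes passed, and up to 4 members of smallest p for each list described. Genes named outside that rule are said to be so. A list of squamous epithelium genes, of which 13 of 18 were measured, was written after the data were seen.

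On simulated data drawn with the spread of the real arrays, where 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold among the 11962, 2-fold changes were recovered for 97% of genes in the challenge in wild type, 95.5% in the challenge in mutant, 97% in either genotype comparison and 88.1% in the interaction. Changes of 1.5-fold were recovered for 64.2%, 61.2%, 74.6%, 64.2% and 29.9% in the order challenge in wild type, challenge in mutant, genotype without challenge, genotype with challenge and interaction. The simulated values were independent between genes, had the same spread in all groups and held no other tissue, so real recovery can be lower. In the real data, larger differences did not pass, such as Cst9 by genotype with challenge (2.27-fold, limma adjusted p = 0.115). The Ccl11 interaction (3.99-fold, limma adjusted p = 0.153) did not pass either. The number of arrays limits the precision.

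Alternatives fixed beforehand were no background model, centring each array on its median, no filter or a stricter one on dim probes, all detected probes, only the arrays compared, eBayes with trend and robust, array weights, the replicate number as a block, a minimum of 1.5-fold, the other list tests and leaving out each array in turn. After the data were seen, a floor at the background limit, the mean of a gene's detected probes, leaving out 3 challenged arrays that carried transcripts of other tissue, and the skeletal muscle score as a covariate were added.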

Results

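Lung RNA of 16 female mice was profiled, 4 in each of the groups untreated wild type, untreated Cox4-2 knockout (mutant), challenged wild type and challenged mutant. The study asked how lungs without Cox4-2, an isoform of subunit IV of cytochrome c oxidase, the last complex of the respiratory chain, respond to ovalbumin challenge, a model of allergic airway inflammation. Each array measured 25697 probes, of which 56.7% to 56.8% lay above background. These shares are nearly equal because the values were quantile normalised and share 1 limit, so they say nothing about array quality. Arrays of a group correlated at rank correlations of 0.945 to 0.967. The first principal component held 38.5% of the variance and separated all challenged from all untreated arrays.

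The targeted gene Cox4i2 was measured by 1 probe (ILMN_2612178), and its signal was lower in the mutant line without being lost. In untreated lungs the intensity was 283 ± 59.8 (SD, n = 4) in wild type and 137 ± 55.9 (SD, n = 4) in mutants, a log2 difference of -0.90 (SE 0.24). The 4 untreated mutant arrays, at 102, 77.5, 181 and 189, all lay below the 4 untreated wild-type arrays, at 247, 252, 260 and 372 (exact permutation p = 0.0286, the smallest possible). In challenged lungs it was 248 ± 55.6 in wild type and 144 ± 66.6 in mutants, a log2 difference of -0.68 (SE 0.24, exact permutation p = 0.0857, n = 4). Mutant challenged array 4, at 243, lay within the challenged wild-type range of 182 to 305. Over both treatments, in a fit chosen after the data were seen, the log2 difference was -0.79 (SE 0.16, stratified exact permutation p = 0.00163), and limma's adjusted p over all genes was 0.0771. Neither comparison within a treatment passed limma's threshold over all genes (adjusted p = 0.19 untreated and 0.265 challenged). The position of the probe relative to the deleted part is not given in the sources used here, and a probe outside the deleted part checks nothing about the labels. Challenge left Cox4i2 at a log2 difference of -0.17 in wild type (SE 0.24, adjusted p = 0.659) and 0.05 in mutants (SE 0.24, adjusted p = 0.894).

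**Figure D1:**
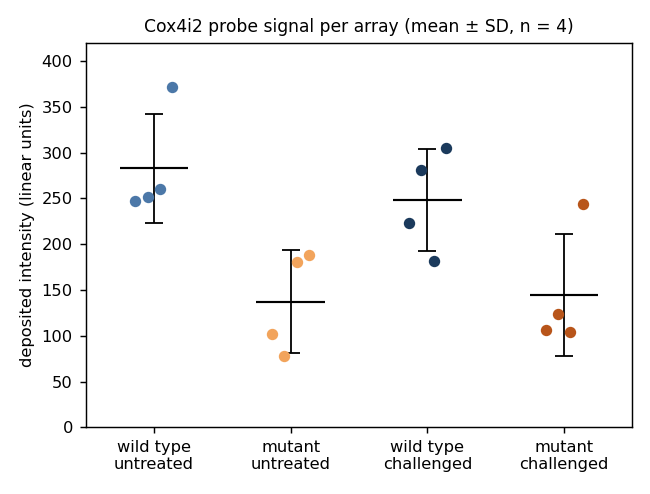
Deposited linear intensity of the Cox4i2 probe on each array by group, with points for arrays and bars for the mean and SD (n = 4). Untreated mutant arrays lie between 77.5 and 189, below untreated wild-type arrays at 247 to 372, and mutant challenged array 4 stands at 243.

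Transcripts of other tissue set 3 challenged arrays apart, wild-type arrays 1 and 3 and mutant array 2. Their skeletal muscle scores were 4.07 to 5.54 log2 units above the untreated wild-type mean, against 0.16 to 0.57 on the other 5 challenged arrays and -0.20 to 0.19 on untreated arrays. Acta1, skeletal muscle actin, reached intensities of 7831 to 16798 on these 3 arrays and at most 148 elsewhere. Krt13, a keratin of squamous epithelium, reached 2263 to 3988 there and at most 75.5 elsewhere. The fat cell hormone gene Adipoq stood at 1463 to 2059 against at most 235 elsewhere, and Glycam1, of lymph node vessels, at 101 to 559 against at most 25.6. Acta1, Krt13, Adipoq and Glycam1 were singled out after their values were seen. Lower levels were also found on some of the other 5 challenged arrays. Acta1 lay between -3.07 and 148 there, against at most 1.06 on untreated arrays, and Krt13 between -8.40 and 75.5 against at most 4.12. Adipoq and Glycam1 were not higher there than on untreated arrays. Without the 3 arrays skeletal muscle genes still rose in 3 of 10 members in wild type and 4 of 10 in mutants (camera adjusted p = 0.0958 and 0.114). Across the arrays, 263 genes moved with the muscle score beyond group differences (limma adjusted p under 0.05), 209 of them higher. Counts without these 3 arrays, or with the muscle score as a covariate, are therefore given beside each comparison.

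In challenged wild-type lungs, genes of allergic airway inflammation were higher and glucocorticoid-responsive genes lower than in untreated ones. The labels record neither time of collection nor handling, so for the glucocorticoid-responsive genes these cannot be told apart from an effect of challenge. The largest rises were in Chil4, a chitinase-like protein of activated macrophages and epithelium, by 27.2-fold (log2 change 4.77, SE 0.58), Rnase2a, an eosinophil-associated ribonuclease, by 15.2-fold, Ccl24, an eosinophil-attracting chemokine, by 11-fold, and Arg1, arginase 1, by 10.1-fold. Clca1 and Muc5ac, products of goblet cells, rose by 8.33-fold and 6.67-fold, and Fxyd4, a regulator of ion pumps, by 6.08-fold. The Clca1 fold is enlarged by wild-type untreated array 2, at a log2 intensity of 8.69 against 11.7 to 12.3 on the other untreated wild-type arrays. Lce3b, a protein of cornified skin, rose at least 5.88-fold, and its intensity was 825 to 1464 on the 3 arrays with other tissue and at most 102 elsewhere. The largest falls were in Map3k6 (log2 change -2.79, SE 0.20), Fam107a (-2.78), Fkbp5, a co-chaperone of the glucocorticoid receptor (-2.74), Rgcc (-2.05), Errfi1, an inhibitor of the EGF receptor (-2.04), the paraoxonase Pon1 (-1.96), Thsd4 (-1.88) and Lrat, which esterifies retinol (-1.83). Their adjusted p lay between 8.15e-07 (Map3k6 and Fam107a) and 0.0192 (Lce3b).

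Among mucous metaplasia genes, 11 of 13 measured members rose (13 adjusted over the list alone), including Ern2 (log2 change 1.65), Bpifb1 (1.21) and Pla2g4c (at least 1.32-fold), at a camera adjusted p of 5.97e-11 (adjusted p = 0.209 with an estimated correlation). Of type 2 cytokines and chemokines, 8 of 13 rose (8 adjusted over the list alone), led by the chemokines Ccl24, Ccl7 (2.28), Ccl11 (1.84) and Ccl12 (1.70), at an adjusted p of 6.24e-06 (adjusted p = 0.111 with an estimated correlation). Of genes of chitinase-like proteins and alternatively activated macrophages, 9 of 15 rose and 1 fell, the same numbers adjusted over the list alone, with Chia1 up by 2.33 and Socs2 at -0.84 (adjusted p = 2.81e-06, and adjusted p = 0.344 with an estimated correlation). Cell cycle genes rose in 22 of 26 members (24 adjusted over the list alone), among them Uhrf1 (1.46), Mcm6 (0.83), Mcm5 (0.95) and Tk1 (1.02), at an adjusted p of 8.29e-15 (adjusted p = 0.344 with an estimated correlation). The cell cycle score was 0.80 ± 0.38 (SD, n = 4), with 0.44 and 0.51 on wild-type challenged arrays 3 and 1, which carried other tissue, and 1.07 and 1.18 on arrays 2 and 4. Glucocorticoid-responsive genes fell in 10 of 14 members (13 adjusted over the list alone), with a median log2 change of -1.51, including Cdkn1a (-1.73), Klf9 (-1.47) and Sgk1 (-1.03), at an adjusted p of 2.55e-09 (adjusted p = 0.111 with an estimated correlation).

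Lymphocyte genes were also higher after challenge in wild type. Of B cell genes 5 of 11 rose (5 adjusted over the list alone), with Cd79b at 1.41, Fcer2a at 0.94 and Cd79a at 1.18 (adjusted p = 0.00016, and adjusted p = 0.361 with an estimated correlation). The B cell score was 0.65 and 0.98 on the wild-type arrays with other tissue and 0.30 and 0.51 on the other 2. Of T cell genes 5 of 19 rose (6 adjusted over the list alone), with Cd27 at 0.70 and Cd3d at 0.62 (adjusted p = 0.00146, and adjusted p = 0.386 with an estimated correlation). Plasma cell genes rose in 2 of 11 members and fell in 1 (3 and 1 adjusted over the list alone), with Fkbp11 at 0.90, Irf4 at 0.70 and Sdc1 at -0.55 (adjusted p = 0.0337, and adjusted p = 0.522 with an estimated correlation). The plasma cell score was 1.15 on wild-type array 1, which carried other tissue, and -0.16 to 0.34 on the other 3. Its median was 0.05 without the 3 arrays with other tissue (adjusted p = 0.765). Interferon response genes rose in 4 of 22 (7 adjusted over the list alone), including Ifi27l2a (1.10) and Isg15 (0.80), at an adjusted p of 0.000478 (adjusted p = 0.446 with an estimated correlation). Extracellular matrix genes rose in 6 of 22, with 7 higher and 1 lower adjusted over the list alone, including Timp1 (1.62), Col3a1 (1.04) and Col1a2 (0.85), at an adjusted p of 0.000507 (adjusted p = 0.386 with an estimated correlation). Acute phase and complement genes rose in 5 of 12 members and fell in 2 (8 and 2 adjusted over the list alone), with Saa3 at 2.54, C1qa at 0.86 and haptoglobin, Hp, at -1.16 (adjusted p = 0.0252, and adjusted p = 0.491 with an estimated correlation).

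Genes of club, ciliated and alveolar type 1 cells and of alveolar macrophages moved the other way. Club cell genes fell in 5 of 10 members (6 adjusted over the list alone), with Cyp2b10 at -1.28 and Gsta3 at -0.89 (adjusted p = 0.000811, and adjusted p = 0.386 with an estimated correlation). Ciliated cell genes fell in 3 of 16 (4 adjusted over the list alone), with Ccdc40 at -0.53 and Cfap206 at -0.64 (adjusted p = 0.0136, and adjusted p = 0.522 with an estimated correlation). The ciliated list had an adjusted p of 0.112 without the 3 arrays with other tissue. Alveolar type 1 genes fell in 2 of 9 (4 adjusted over the list alone), with Gprc5a at -0.63 (adjusted p = 0.019, and adjusted p = 0.429 with an estimated correlation). Alveolar macrophage genes fell in 2 of 9 (2 adjusted over the list alone), with Car4 at -0.65 and Abcg1 at -0.68 (adjusted p = 0.0419, and adjusted p = 0.491 with an estimated correlation).

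Respiratory chain genes outside complex IV rose in 17 of 56 members (22 adjusted over the list alone), with Ndufb10 at 0.78 and Sdhd at 0.67, and a median log2 change of 0.24 (adjusted p = 2.74e-09, and adjusted p = 0.386 with an estimated correlation). Cytochrome c oxidase genes other than Cox4i2 rose in 4 of 27 (3 adjusted over the list alone), with Cox4i1, the other isoform of subunit IV, at 0.48 (adjusted p = 0.0196, and adjusted p = 0.475 with an estimated correlation). Skeletal muscle genes rose in 4 of 10 (10 adjusted over the list alone), with Acta1 up at least 20-fold (adjusted p of the list 0.000279, and adjusted p = 0.471 with an estimated correlation). The scores of the respiratory chain list were 0.36 and 0.38, and those of the oxidase list 0.38 and 0.41, on the wild-type arrays with other tissue, against 0.08 and 0.17, and -0.06 and -0.00, on the other 2. With the muscle covariate the calls of B cell (adjusted p = 0.0712), plasma cell (0.715), acute phase (0.0657), oxidase (0.526), alveolar type 1 (0.0887), ciliated cell (0.0963) and skeletal muscle genes (0.715) were lost. Without the 3 arrays the adjusted p was 0.0715 for the respiratory chain, 0.969 for the oxidase and 0.0958 for skeletal muscle genes, and the oxidase list then had a median of 0.03 while the test pointed down. Cardiac muscle (median -0.79, adjusted p = 0.00228) and fat genes (-0.82, 0.0317) then passed as lower, with an adjusted p = 0.481 and an adjusted p = 0.469 with an estimated correlation. Both also passed with the covariate (0.00138 and 0.0209, and adjusted p = 0.555 and adjusted p = 0.452 with an estimated correlation). The other lists did not pass camera, at adjusted p of 0.064 for eosinophil, endothelial cell and antigen presentation genes, 0.114 for the circadian clock, and 0.194 to 0.947 for red blood cell, antioxidant, fat, alveolar type 2, Cox4i2 neighbour, neutrophil, sex and strain check, pericyte, immediate early and heat shock, mast cell and basophil, smooth muscle, cardiac muscle, NK cell, hypoxia and glycolysis, and thymus genes. Of these, fry called antioxidant (adjusted p = 0.0113), Cox4i2 neighbour (0.0363) and circadian clock genes (0.0443), all as lower.

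In all, 2108 genes changed with challenge in wild type, 980 higher and 1128 lower, of which 120 rose and 87 fell by at least 2-fold. In 2141 genes (17.9%) the 4 challenged arrays did not overlap the 4 untreated ones, against 2.86% by chance. That share is the mean over all splits of the arrays, and its spread between splits was not computed. The count was 2391 without the 3 arrays with other tissue and 2074 with the muscle score as a covariate. It was 1220 when only these 8 arrays were fitted.

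**Figure D2:**
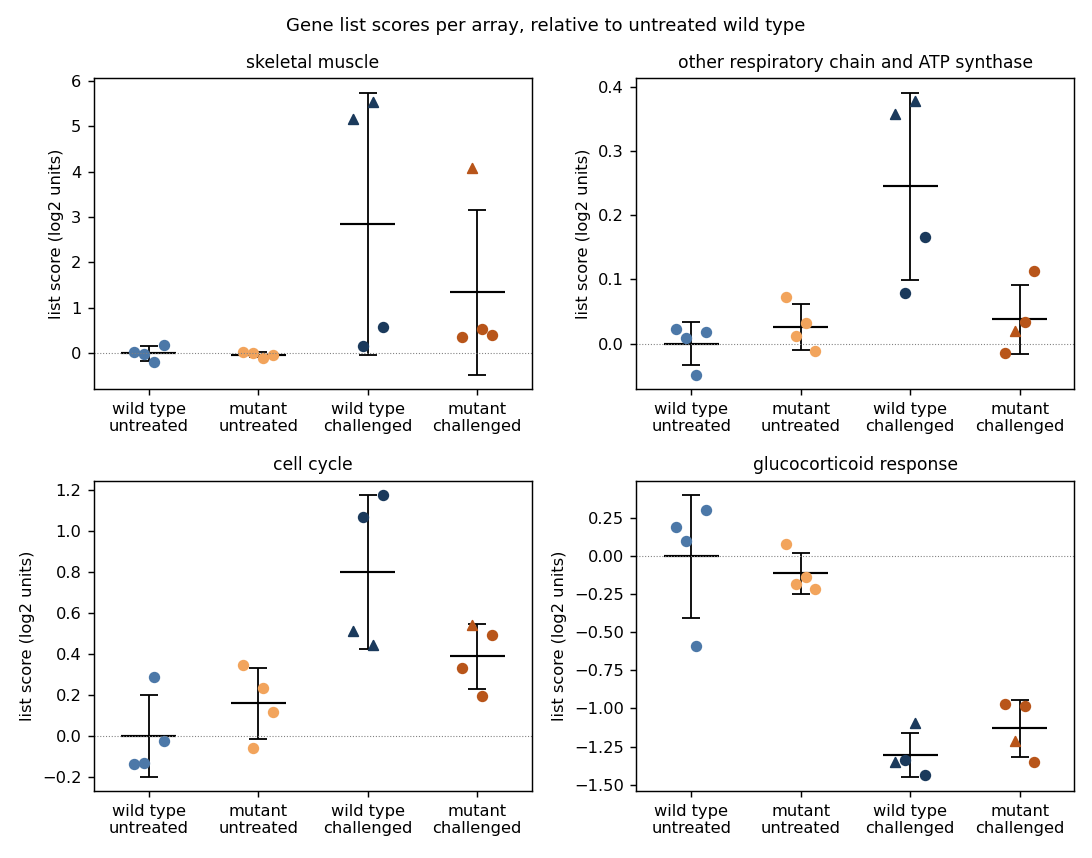
Scores of 4 gene lists on each array (mean log2 value of the members, relative to the untreated wild-type mean), with points for arrays, triangles for the 3 challenged arrays with other tissue, and bars for the mean and SD (n = 4). The triangles stand at 4.07 to 5.54 for skeletal muscle, while glucocorticoid scores of all 8 challenged arrays lie between -1.44 and -0.97.

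In challenged mutant lungs the same leading glucocorticoid-responsive gene was lower, and goblet cell and lymphocyte genes were higher, than in untreated ones. As in wild type, time of collection and handling cannot be told apart from an effect of challenge on the glucocorticoid-responsive genes. Fkbp5 fell by 3.18 on the log2 scale (SE 0.25), and Map3k6 (-2.93) and Fam107a (-2.76) fell as well. Falls were also found in the fibrinogen gene Fga (at least 3.11-fold), Rgcc (-1.86), Cdkn1a, an inhibitor of cell division (-1.83), Myrip (-1.82) and Lyve1, a receptor of lymphatic vessels (-1.66). The largest rises were in Chil4 (5.99-fold, log2 change 2.58, SE 0.58), Muc5ac (5.15-fold), the acute phase gene Saa3 (3.41-fold), the collagenase Mmp13 (3.25-fold), intelectin, Itln1 (3.09-fold), the immunoglobulin transporter Pigr (3.04-fold) and the chemokines Ccl4 (3.01-fold) and Ccl7 (2.91-fold). Adjusted p of these genes lay between 5.3e-07 (Map3k6 and Fam107a) and 0.0213 (Saa3).

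Of the 37 lists, 4 passed in mutants. Glucocorticoid-responsive genes fell in 8 of 14 members (10 adjusted over the list alone), with Klf9 at -1.24 and Tsc22d3 at -1.10 and a median of -1.07 (adjusted p = 1.63e-05, and adjusted p = 0.547 with an estimated correlation). Mucous metaplasia genes rose in 10 of 13 (11 adjusted over the list alone), with Tff2 at 1.48, Ern2 at 1.05 and Foxa3 at 0.97 (adjusted p = 3.22e-05, and adjusted p = 0.828 with an estimated correlation). T cell genes rose in 8 of 19 (11 adjusted over the list alone), with Cd27 at 0.80, Cd3d at 0.82 and Lat at 0.50 (adjusted p = 0.00153, and adjusted p = 0.828 with an estimated correlation). B cell genes rose in 4 of 11 (4 adjusted over the list alone), with Blk at 1.37, Cd79b at 1.25 and Cxcr5 at 0.79 (adjusted p = 0.00211, and adjusted p = 0.828 with an estimated correlation). The B cell score was 0.87 on mutant array 2, which carried other tissue, and 0.29 to 0.34 on the other 3. The remaining 33 lists had adjusted p of 0.0545 (neutrophil) to 0.952, among them cell cycle (median 0.26, adjusted p = 0.176), type 2 (0.17, 0.241) and the cytochrome c oxidase genes (-0.06, 0.612). Fry called the neutrophil list as higher (adjusted p = 0.0388). With the muscle covariate 2 more lists passed. Cell cycle genes then rose in 8 of 26 members, against 3 in the fit of all arrays (median 0.37, adjusted p = 0.0134, and adjusted p = 0.902 with an estimated correlation). Smooth muscle genes fell in 7 of 17 and rose in 1 (median -0.24, adjusted p = 0.0134, and adjusted p = 0.902 with an estimated correlation). The smooth muscle list also passed without the 3 arrays with other tissue (median -0.255, adjusted p = 0.0326, and adjusted p = 0.941 with an estimated correlation), while cell cycle genes did not (median 0.21, adjusted p = 0.228).

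Altogether 2843 genes changed with challenge in mutants, 1448 higher and 1395 lower, of which 78 rose and 68 fell by at least 2-fold. Groups did not overlap in 3540 genes (29.6%, against 2.86% by chance). The count was 2525 without the 3 arrays with other tissue and 3341 with the muscle score as a covariate. In 71 genes different probes were called in opposite directions, against 3 genes for the challenge in wild type, so the direction of such a gene rests on the probe chosen. A score of the differences between probes of a gene, chosen after the data were seen, went from -2.58 ± 1.54 (SD, n = 4) to 5.18 ± 2.91 with challenge in wild type and from -7.5 ± 0.876 to 4.9 ± 1.96 in mutants, so the counts of 2108 and 2843 genes came with a shift at the level of probes. Without mutant untreated array 1, 7 lists passed in place of 4.

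The 2 challenge responses were alike across genes, with Pearson's r = 0.704 and Spearman's rho = 0.641 over 11962 genes, which are not independent replicates. Of the changed genes, 542 rose in both genotypes against 119 expected of independent lists, and 595 fell in both against 131.5. Only 2 genes changed in opposite directions. Of 3812 genes called in either genotype, 969 were called in wild type only and 1704 in mutants only. Over these 3812 genes the slope of the mutant on the wild-type log2 change, through 0, was 0.734. Noise in the wild-type change lowers such a slope, and arrays with other tissue entered both responses. The slope therefore does not show a weaker response in mutants. The 2 responses share no arrays.

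**Figure D3:**
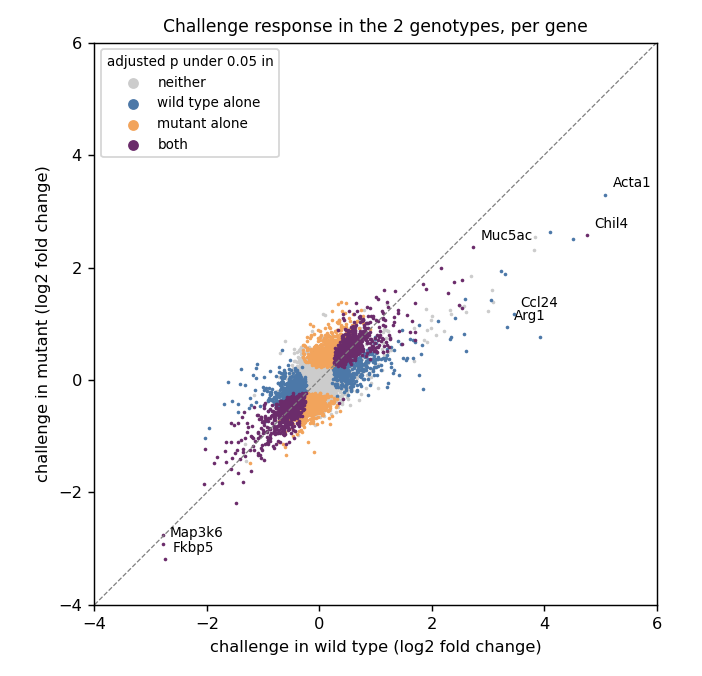
Log2 fold change of each of 11962 genes after challenge in wild type (horizontal) and in mutants (vertical), coloured by the genotype in which limma's adjusted p was under 0.05, with a dashed line of equal change. Fkbp5 and Map3k6 lie near that line, while Chil4 (4.77 in wild type and 2.58 in mutants) lies below it.

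In untreated lungs, 0 genes differed between mutant and wild type (limma, 1454 genes at an unadjusted p under 0.05, smallest adjusted p 0.0791). The 10 genes of smallest p, none past the threshold, were Slc22a5, a carnitine transporter (log2 difference -0.62), Mvb12b (-0.58), Arf6 (-0.53), Zfp207 (0.62), Rapgef1 (-0.63), Ctdspl2 (0.52), U2af1l4 (-0.54), the netrin receptor Unc5b (-0.64), Noxa1 (at least 1.33-fold lower) and the B cell kinase Blk (-0.93), with adjusted p of 0.0791 to 0.143. As groups, 3 lists were higher in mutants although 0 of their members passed over all genes. These were mucous metaplasia genes (median 0.39, with 2 members adjusted over the list alone, Clca1 at 1.82, adjusted p = 0.000793), chitinase-like and alternatively activated macrophage genes (median 0.40, 4 members adjusted over the list alone, Retnla at 1.62, Chil4 at 1.82, adjusted p = 0.00105) and cell cycle genes (median 0.21, 1 member adjusted over the list alone, Mad2l1 at 0.46, adjusted p = 0.012). Each of the 3 had an adjusted p = 0.838 with an estimated correlation, and fry called none of the 37 lists. Wild-type untreated array 2 had a mucous score of -0.57 against 0.11 to 0.24 on the other 3, and a Clca1 log2 intensity of 8.69 against 11.7 to 12.3. Its low signal enlarges the Clca1 difference of 1.82. Wild-type untreated array 3 had a cell cycle score of 0.29 against -0.14 to -0.02. The other 34 lists had adjusted p of 0.0567 to 0.994, including the oxidase genes (median 0.04, 0.25).

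Groups did not overlap in 849 genes (7.1%, against a mean of 2.86% over all splits of the arrays). Genes are correlated and the spread between splits was not computed, so no excess due to genotype can be read from this share. The count of 0 became 130 with array weights, 36 without wild-type untreated array 3 and 2 without mutant untreated array 2, and the lists passing were 11 without wild-type untreated array 3, 5 without array 4 and 7 without mutant untreated array 2. It stayed 0 without the 3 arrays with other tissue and with the muscle score as a covariate.

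In challenged lungs 2 features were lower in mutants and 0 higher. Gamt, which makes creatine, stood at 136 ± 8.48 (SD, n = 4) in wild type and 81.4 ± 10.5 in mutants, a log2 difference of -0.53 (SE 0.08, adjusted p = 0.0475). The unnamed probe ILMN_1228010, outside the naming rule and named because the count is small, stood at 119 ± 33.6 against 18.7 ± 16.8 (-1.44, adjusted p = 0.00302). The next genes by p did not pass, with log2 differences for Prdx4 of -0.57, Uck2 -0.60, Ccdc80 -1.003, Cst9 -1.18, Capn6 -0.61, Eif2s2 0.68, Tubb6 -0.55, Cdh26 0.68 and Ifi27l2a -0.76 (adjusted p = 0.0549 to 0.14). Limma gave 1465 genes at an unadjusted p under 0.05, and groups did not overlap in 784 (6.55%, against a mean of 2.86% over all splits). As in untreated lungs, no excess due to genotype can be read from this share.

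As groups, 14 lists differed between challenged mutants and wild type with the preset correlation, with 0 members past the threshold over all genes in each. Lower in mutants were cell cycle genes (median -0.46, 10 of 26 adjusted over the list alone, Mcm5 at -0.55, Cdca3 at -0.78, adjusted p = 3.7e-13, and adjusted p = 0.46 with an estimated correlation) and extracellular matrix genes (median -0.31, 8 of 22 adjusted over the list alone, Col6a1 at -0.57, Col1a1 at -0.72, adjusted p = 1.57e-08, and adjusted p = 0.253 with an estimated correlation). Type 2 genes were lower (median -0.34, 3 of 13 adjusted over the list alone, Ccl24 at -2.08, Ccl11 at -0.93, adjusted p = 0.000131, and adjusted p = 0.253 with an estimated correlation), as were plasma cell genes (-0.34, 3 of 11, Fkbp11 at -0.82, adjusted p = 7.99e-05, and adjusted p = 0.527 with an estimated correlation). Interferon response (-0.13, 3 of 22, 0.00334), acute phase and complement (-0.39, 0 of 12, 0.0314), chitinase-like (-0.15, 2 of 15, 0.0371), eosinophil (-0.05, 2 of 7, with Prg2 at -1.04, 0.0487) and smooth muscle genes (-0.16, 0 of 17, 0.0186) were also lower, given as median, members adjusted over the list alone and adjusted p. With an estimated correlation the chitinase-like list had an adjusted p = 0.596 and the other 4 lists an adjusted p = 0.537. Higher in mutants were ciliated cell genes (0.32, 0 of 16, adjusted p = 2.9e-05, and adjusted p = 0.463 with an estimated correlation) and club cell genes (0.37, 3 of 10, Aldh1a1 at 0.44, adjusted p = 0.000347, and adjusted p = 0.46 with an estimated correlation).

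The lists of energy metabolism were lower in challenged mutants than in challenged wild type, where the 2 arrays with other tissue held the highest scores. Mutant array 2 carried other tissue too. Its oxidase score of -0.04 and respiratory chain score of 0.02 lay within those of the other 3 mutant challenged arrays (-0.06 to 0.09 and -0.01 to 0.11). Respiratory chain genes had a median of -0.20 (0 of 56 adjusted over the list alone, Ndufb2 at -0.48, Cyc1 at -0.42, adjusted p = 2.79e-16, and adjusted p = 0.253 with an estimated correlation). Cytochrome c oxidase genes had a median of -0.08 (0 of 27 adjusted over the list alone, Cox5a at -0.35, Cox4i1 at -0.23, adjusted p = 0.000347, and adjusted p = 0.46 with an estimated correlation), and skeletal muscle genes one of -1.49 (0 of 10 adjusted over the list alone, adjusted p = 0.000617, and adjusted p = 0.537 with an estimated correlation). Without the 3 arrays the medians were -0.08 for respiratory chain genes (adjusted p = 0.0213, and adjusted p = 0.524 with an estimated correlation), 0.02 for oxidase genes (0.797) and 0.11 for skeletal muscle genes (0.867). Plasma cell genes then had a median of -0.09 (adjusted p = 0.149) and smooth muscle genes one of -0.03 (0.706), so these calls were lost too. Type 2 (-0.625, 0.000133), chitinase-like (-0.307, 0.000445) and eosinophil genes (-0.327, 0.00834) kept their calls, with lower medians than with all arrays. With an estimated correlation these had an adjusted p = 0.153, 0.462 and 0.452. With the muscle covariate the calls of smooth muscle (0.261), skeletal muscle (0.867) and eosinophil genes (0.156) were lost, and oxidase (median -0.08, adjusted p = 0.00921) and respiratory chain genes (-0.15, 5.17e-10) passed, with an adjusted p = 0.544 and an adjusted p = 0.3 with an estimated correlation. Those not passing among the 37 lists had adjusted p of 0.06 (alveolar type 1) to 0.905, and fry called 0 lists. Among them were mucous metaplasia genes, with a median of 0.09 and a test that pointed down (adjusted p = 0.905). This mucous list was lower in mutants without the 3 arrays, with a median of -0.31 (adjusted p = 0.0034, and adjusted p = 0.524 with an estimated correlation).

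Without the 3 arrays, which left 2 wild-type and 3 mutant challenged arrays, 86 genes differed, 63 lower and 23 higher in mutants. With the muscle score as a covariate the count was 5, with 2 higher and 3 lower. Lower among the 86 were Ccl24 (-3.16), the acute phase gene Saa3 (-2.46), Timp1 (-1.43), the collagen genes Col1a1 (-1.01) and Col3a1 (-0.89), and the cell division genes Plk1 (-0.99), Birc5 (-1.09), Mcm5 (-0.90) and Tk1 (-0.98), chosen after their values were seen. Higher among them were Adipoq (1.62), which also moved with the muscle score, Inmt (1.09) and Cyp4b1 (0.89). Markers of other tissue thus still differed between these 5 arrays, with fat genes at a median of 0.86 (adjusted p = 0.000719, and adjusted p = 0.452 with an estimated correlation) and cardiac muscle genes at 0.42 (adjusted p = 0.000875, and adjusted p = 0.524 with an estimated correlation). Alveolar macrophage (0.32, 0.00424) and alveolar type 1 genes (0.20, 0.0239) passed as higher too, with an adjusted p = 0.462 and an adjusted p = 0.475 with an estimated correlation. With the covariate, fat (0.17, 0.0174), cardiac muscle (0.23, 0.0287) and alveolar macrophage genes (0.24, 0.0012) passed, with an adjusted p = 0.542, 0.709 and 0.521 with an estimated correlation. Fat scores were -0.68 and -0.99 on wild-type challenged arrays 2 and 4 and -0.42 to 0.14 on the 3 mutant arrays. Cell cycle genes then had a median of -0.80 (7 of 26 lower over all genes, adjusted p = 1.65e-27, and adjusted p = 0.0912 with an estimated correlation), and extracellular matrix genes one of -0.50 (5 of 22, adjusted p = 5.32e-15, and adjusted p = 0.0492 with an estimated correlation). The count of 2 was 13 without mutant challenged array 2 alone and 1 without each of 12 other arrays in turn.

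No gene passed the test of whether the challenge response differed between genotypes (0 genes by limma, 1434 at an unadjusted p under 0.05, smallest adjusted p 0.153). The 10 genes of smallest p, none past the threshold, were Ncapd3 (-0.77), Prdx4 (-0.75), Ccl11 (3.99-fold weaker in mutants), Uck2 (-0.75), Depp1 (1.39), Hspa1a (-1.17), Mad2l1 (-0.79), Tcf7l2 (0.69), Mark1 (mutants at background after challenge) and Zfp207 (-0.76), given as the log2 response of mutants minus that of wild type. For Ccl11, the intensity went from 132 ± 48 to 564 ± 80.8 (SD, n = 4) in wild type and from 345 ± 182 to 275 ± 18.4 in mutants. By list, 13 differed with the preset correlation. Cell cycle genes had a median difference of -0.65 (7 of 26 adjusted over the list alone, Tyms at -0.87, adjusted p = 6.79e-13, and adjusted p = 0.366 with an estimated correlation). Chitinase-like (-0.49, 6 of 15, Chia1 at -1.59, 2.75e-05), type 2 (-0.64, 2 of 13, 0.000136), extracellular matrix (-0.45, 1 of 22, 2.75e-05), respiratory chain (-0.20, 10 of 56, Atp5o at -0.66, 3.61e-11), cytochrome c oxidase (-0.20, 0 of 27, 0.000176) and club cell genes (0.47, 0 of 10, 0.000261) each had an adjusted p = 0.366 with an estimated correlation. Interferon response (-0.23, 1 of 22, 0.000176), ciliated cell (0.37, 0 of 16, 0.000317), mucous metaplasia (-0.37, 0 of 13, 0.00463) and alveolar type 2 genes (0.12, 2 of 16, 0.0452) had an adjusted p = 0.557 with an estimated correlation. With all arrays the mucous score was 1.48 in challenged wild type and 1.49 in challenged mutants, so its difference came from untreated lungs. There mutants stood at 0.47 relative to wild type, whose array 2, at -0.57, lay apart. The chitinase-like score was 0.59 in untreated mutants, and 1.45 and 1.17 in challenged wild type and mutants, so its difference came in part from untreated lungs too. Plasma cell (-0.36, 1 of 11, 0.00939) and skeletal muscle genes (-1.50, 0 of 10, 0.017) had an adjusted p = 0.586 and an adjusted p = 0.679 with an estimated correlation. Lost without the 3 arrays with other tissue were the calls of plasma cell (median -0.12, adjusted p = 0.361), oxidase (-0.03, 0.569), skeletal muscle (0.17, 0.799) and alveolar type 2 genes (0.14, 0.104). Cell cycle genes then stood at -1.09 (adjusted p = 7.8e-29, and adjusted p = 0.0795 with an estimated correlation). Calls gained there, all higher, were fat (1.07, 0.00074), cardiac muscle (0.72, 1.23e-05), alveolar macrophage (0.44, 0.00562), pericyte (0.25, 0.00479) and alveolar type 1 genes (0.17, 0.0188). These had an adjusted p = 0.305 (fat and pericyte) to 0.437 with an estimated correlation. With the muscle covariate the calls of plasma cell (0.09) and skeletal muscle genes (0.8) were lost. Fat (0.37, 0.0192), cardiac muscle (0.48, 0.000534), alveolar macrophage (0.56, 0.00479) and pericyte genes (0.22, 0.0192) then passed, with an adjusted p = 0.422 to 0.477 with an estimated correlation. In each of the 13 lists 0 members passed over all genes in the fit of all arrays, fry called 0 lists, and the other 24 had adjusted p of 0.0605 to 0.951. Without the 3 arrays with other tissue 34 genes passed, 11 with a higher and 23 with a lower response in mutants, 29 of them among the 86 above, and with the muscle covariate 0 passed (1333 at an unadjusted p under 0.05). Without wild-type untreated array 3 the count was 3, and without mutant untreated array 2 it was 1.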

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

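The tests of other tissue, time of day, handling, the region around Cox4i2, probe variants and a wrong label, and the splits without 3 arrays, were chosen only after the result was seen, while leaving out single arrays and the splits of all arrays were planned.

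Of the lists lower in mutant than in wild-type challenged lungs, some grew and others shrank when the 3 challenged arrays with other tissue were left out. The cell cycle list went from a median of -0.459 to -0.801, against other tissue on these 3 arrays as its source, and its highest adjusted p without any 1 array was 1.03e-07 at the preset correlation, where no single array decided it, though with all arrays the adjusted p was 0.46 with an estimated correlation. The cytochrome c oxidase list went from -0.0829 to 0.0158 and the respiratory chain list from -0.201 to -0.0822, but mutant challenged array 2, with a muscle score of 4.07, scored -0.043 and 0.02, within its group, and with the muscle covariate both calls held at the preset correlation (-0.0841, adjusted p = 0.00921, and -0.153, adjusted p = 5.17e-10) and not with an estimated one (0.544 and 0.3), so other tissue cannot be told apart from genotype for these 2 lists. Of 35 splits of the 8 challenged arrays, 7 gave at least the real 2 genes, the highest other 114, so chance cannot be excluded, and the 3 splits with most genes (114, 40 and 35) put the 3 arrays with other tissue on 1 side, a structure of the samples. Without those arrays the real count of 86 was reached by 1 of 10 splits (highest other 8), too few splits for a share under 0.05, fat genes still differed between the 5 arrays left (median 0.855), and an effect of genotype on dividing cells remains open.

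Glucocorticoid-responsive genes were lower after challenge in both genotypes, with medians of -1.51 in wild type and -1.07 in mutants. Other tissue was argued against by medians of -1.66 and -0.912 without the 3 arrays. Time of day stays open, as the labels record no time and the largest change among 15 clock genes, Per1 (-2.03 in wild type and -1.03 in mutants, SE 0.425), belongs to the glucocorticoid list as well, while in wild type the next largest were Per2 (-0.881, SE 0.198) and Cry2 (-0.871, SE 0.26), Bhlhe40 (0.693) passed as well, and Arntl (-0.195), Clock (-0.183), Nr1d1 (-0.446), Dbp (0.345), Per3 (-0.0656) and Tef (0.0492) did not, and in mutants Per2 (-0.88), Nfil3 (-0.5), Per3 (0.377) and Clock (-0.286) passed and Tef (0.771) and Dbp (0.711) did not. The clock list as a whole was lower in wild type by fry (adjusted p = 0.0443) and not by camera (0.114), and in mutants by neither (0.746 and 0.84). A higher stress hormone level or different handling of the untreated mice could give the same medians of -1.51 and -1.07 and cannot be told apart from an effect of challenge, since the labels record neither. For the challenge counts, 1 of 35 splits reached the 2108 genes in wild type (highest other 133) and 1 of 35 the 2843 in mutants (highest other 1). In each case this was the real split, the smallest share possible, which argues against chance. Such splits cannot show a batch shared by the arrays of a group.

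Zcchc3 and the probe ILMN_1228010 were lower in the mutant line together with Cox4i2. A sequence difference under 1 probe was argued against for Zcchc3, where the highest p of the 3 probes was 0.00393, and stays open for ILMN_1228010, measured by 1 probe alone. A region around Cox4i2 shared by the mutant line may be the source but was not settled. Neighbours were taken from the 25 protein-coding genes on either side of Cox4i2, so a longer region was not tested. Of 29 other measured neighbours 13.8% differed at an unadjusted p under 0.05, and of other genes 11.3% (Fisher's exact p = 0.564). Over both treatments, 5 of 22 genes with a limma adjusted p under 0.1 and a known chromosome lay on chromosome 2. Cox4i2 and Zcchc3 are among them, and the share of all genes on chromosome 2 was not computed. The unnamed probe ILMN_1228010 is not in this count. The deposited non-normalised table names ILMN_1228010 Rem1, which places it among the neighbours, and an effect of losing Cox4i2 itself was not tested. Mutant challenged array 4 had a Cox4i2 signal in the wild-type range. Its ILMN_1228010 intensity of 42.7 lay below the lowest challenged wild-type array at 83.4, and its Zcchc3 intensity of 258 below the lowest at 314. That Zcchc3 value lay within the untreated wild-type range of 219 to 359. Both probes were picked as lower in mutants from fits that hold this array, so they cannot decide whether the mouse was wild type. A mouse with 1 intact copy stays open too. Mutant untreated arrays 3 and 4 also had higher Cox4i2 (181 and 189) and Zcchc3 signals (172.5 and 218) than the other untreated mutants.

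For genotype without challenge and for the interaction the real count was 0, which all 35 of 35 and 100 of 100 splits reach by construction, so the splits decide nothing there (highest other 20 and 34).

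Single arrays lay far from the other 3 of their group in 8 of 148 list scores and 12 of 216 gene values, where chance gives about 1 in 20. Among list scores, in log2 units, these were type 2 genes on mutant challenged array 3 (0.24 against 0.657 to 0.74), mucous genes on wild-type untreated array 2 (-0.574 against 0.107 to 0.239), and neutrophil genes on wild-type untreated array 1 (0.702 against -0.322 to -0.162) and mutant challenged array 2 (0.589 against 0.138 to 0.162). On mutant challenged array 2 the B cell score was 0.868 (others 0.292 to 0.337) and the skeletal muscle score 4.07 (others 0.358 to 0.534). The fat score of wild-type untreated array 3 was -0.435 (others 0.139 to 0.157), and the sex and strain check score of wild-type challenged array 2 was 0.0137 (others 0.154 to 0.18). Among genes, in log2 intensity, wild-type untreated array 4 stood apart for Cox4i2 (8.69), array 2 for Clca1 (8.69), array 1 for Lrat (6.62) and array 3 for Mmp13 (8.44), Rapgef1 (8.93), Ncapd3 (8.35) and Mad2l1 (7.85). Wild-type challenged array 3 stood apart for Fxyd4 (7.93) and array 2 for Cdkn1a (9.79). Mutant challenged array 3 stood apart for Ccl7 (7.32), and mutant untreated arrays 3 and 4 for Unc5b (6.17) and Cdh26 (6.41).

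The challenge response of 13 lists differed between genotypes by the interaction test with the preset correlation and 0 with an estimated one. The median differences, mutant minus wild type, were -0.646 for cell cycle, -0.2 for respiratory chain, -0.487 for chitinase-like, -0.452 for extracellular matrix, -0.641 for type 2, -0.231 for interferon response, -0.197 for cytochrome c oxidase, -0.372 for mucous metaplasia, -0.359 for plasma cell and -1.5 for skeletal muscle genes. They were 0.47 for club cell, 0.368 for ciliated cell and 0.119 for alveolar type 2 genes. For mucous metaplasia genes the challenged scores were alike with all arrays (1.48 in wild type and 1.49 in mutants), so that difference came from untreated lungs.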

How the results depend on the processing

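The floor, the mean of probes, leaving out 3 arrays with other tissue and the muscle covariate were chosen after seeing the data, and the other alternatives before. Where not stated otherwise below, the cause was not tested. The correlation of the 2 challenge responses ranged from 0.622 (without mutant challenged array 2) to 0.745 (muscle covariate).

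Genes differing by genotype with challenge numbered 4 with log2(value + 50), median centring, trend and robust, or the mean of probes, 1 with no filter, all probes, array weights, the replicate block, at least 1.5-fold or the floor, 0 with only the arrays compared, 86 without the 3 arrays, 5 with the covariate, and 1 to 13 leaving out single arrays. Without challenge they numbered 2 (stricter filter), 3 (all probes), 1 (trend and robust, floor, or mean of probes), 130 (array weights) and 0 to 36 leaving out single arrays. In the interaction they numbered 34 without the 3 arrays and 0 to 3 leaving out single arrays. Challenge changed 1220 genes in wild type with only the arrays compared, and 811 in wild type and 863 in mutants at 1.5-fold, which by construction counts fewer genes. Leaving out single arrays gave 1418 to 2513 in wild type and 2042 to 3106 in mutants.

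In the fit of all arrays, 0 lists passed in each of the 5 contrasts with an estimated correlation, and with fry 0 in the genotype contrasts and the interaction. For challenge in wild type fry did call lists, among them glucocorticoid (adjusted p = 4.64e-05), type 2 (0.000186), mucous metaplasia (0.000559) and cell cycle genes (0.00304). Plasma cell, alveolar macrophage, acute phase, oxidase, ciliated cell and skeletal muscle genes did not pass fry (0.0536 to 0.174). In mutants fry called glucocorticoid (0.000463), T cell (0.0127), mucous metaplasia and B cell (0.0129 each) and neutrophil genes (0.0388). Leaving out single arrays, 15 to 23 lists passed for challenge in wild type, 4 to 7 in mutants, 2 to 11 for genotype without challenge, 10 to 16 with challenge and 11 to 18 for the interaction.

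The small challenge difference of Cox4i2, not past the threshold, turned to 0.0609 in wild type without the 3 arrays and 0.0523 with the covariate. Leaving out single arrays it ranged from -0.263 to -0.0464 in wild type and -0.172 to 0.195 in mutants (-0.0335, -0.124 and -0.172 without mutant untreated arrays 1 and 2 and mutant challenged array 4), and its interaction from -0.00269 (without mutant challenged array 4) to 0.364. Its genotype difference kept its sign, at -1.04 to -0.724 untreated and -0.904 to -0.58 challenged.

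Other directions turned without the 3 arrays, for Atp2a1 (0.083 with challenge by genotype, 0.134 in the interaction), for the oxidase list (adjusted p 0.969 for challenge in wild type and 0.797 for genotype with challenge) and for the skeletal muscle list (0.867 and 0.799 for genotype with challenge and interaction, and 0.715 for challenge in wild type with the covariate). Il5ra by genotype with challenge, not past the threshold, turned to 0.0508 with the covariate, and to 0.052 and 0.0171 without wild-type challenged array 1 and mutant challenged array 4 (lowest -0.163 without mutant challenged array 2). Pla2g4c by genotype without challenge became 0 at the floor, where both groups lie at the limit. Apart from Cox4i2, among 7066 alternatives of 256 named gene results, 6800 kept direction and side of the threshold, 167 lost and 93 gained a call and 6 turned. Among 1300 of 52 list results, 1124 kept them, 171 lost the call and 5 turned.

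The replicate numbers do not pair the samples, since 24 same-numbered pairs had a median correlation of -0.0132 (-0.496 to 0.262), with 3 above 0.1, and 5 of 16 arrays correlated best with an array of their own number. The replicate block gave 1986, 2775, 0, 1 and 0 genes in the 5 contrasts. A slide block was not run, as the sources used here give none, the deposited values were already the source, and median centring came on top of their quantile normalisation. Probes near the background limit of 16.8 have understated folds.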

Other observations

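The fit over both treatments, the squamous epithelium list, the counts of probe pairs and the probe score were chosen only after results had been seen.

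Over all 16 arrays, with genotype compared across both treatments, 7 genes were lower in mutants and 0 higher (limma, 1358 genes at an unadjusted p under 0.05). They were Gamt (log2 difference -0.41, SE 0.07), Crym, a thyroid hormone-binding protein (-0.40), Tbrg4 (-0.47), Unc5b (-0.53), Zcchc3 (-1.25, SE 0.22) and the unnamed probes ILMN_1228010 (-1.04) and ILMN_2712066 (-0.41), with adjusted p of 0.0161 to 0.0367. The main Zcchc3 probe stood at 303 ± 61 (SD, n = 4) in untreated wild type, 130 ± 77.9 in untreated mutants, 358 ± 59.2 in challenged wild type and 125 ± 89.5 in challenged mutants. Across the 8 mutant arrays the log2 signals of Cox4i2 and Zcchc3 rose and fell together (Pearson's r = 0.922, permutation p = 0.00377, adjusted p = 0.0113 over 3 pairs, Spearman's rho = 0.786, permutation p = 0.0279). The correlation was 0.937 among untreated and 0.918 among challenged mutants, and 0.78 without the 2 arrays farthest from the median. Mutant untreated arrays 3 and 4 and mutant challenged array 4 were highest for both, at intensities of 181, 189 and 243 for Cox4i2. Their Zcchc3 intensities were 172.5, 218 and 258, while the other mutant arrays reached at most 124 for Cox4i2 and 98.3 for Zcchc3. The value of 0.78 still includes mutant untreated array 3, so a graded relation among the lower arrays is not shown. For Cox4i2 and ILMN_1228010 r was 0.603 (permutation p = 0.116, rho = 0.405, permutation p = 0.327) and -0.0133 without 2 arrays. For Zcchc3 and ILMN_1228010 r was 0.738 (permutation p = 0.0454, adjusted p = 0.0681, rho = 0.619, permutation p = 0.115) and 0.254 without 2 arrays. Over all 8 arrays these 2 relations rest on those 2 arrays, while within untreated and challenged mutants r was 0.59 and 0.866 for the first pair and 0.751 and 0.924 for the second, over 4 arrays each.

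The 3 challenged arrays with muscle transcripts also carried genes of stratified epithelium. Of 13 measured squamous epithelium genes, 12 were higher with the muscle score (limma adjusted p under 0.05). The list was written after these arrays had been seen, so this count is a description and not independent support. Its scores were 3.03 to 3.69 on these arrays, 0.12 to 0.71 on the other challenged arrays and at most 0.04 on untreated ones. Krt13, Lor, Krtdap, Krt4 and Lce3c moved by 1.28, 1.26, 1.05, 0.89 and 0.76 log2 units per unit of the muscle score.

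Probes of the same gene differed in their response to challenge. Among 1978 genes with 2 detected probes, both probes were called in opposite directions in 27 genes for the challenge in mutants and in 0 for the challenge in wild type, and the changes of the 2 probes correlated across genes at 0.447 and 0.668. The leading component of the differences between probes of a gene held 35.5% of their variance. Its score was -7.5 ± 0.876 (SD, n = 4) in untreated mutants and -2.58 ± 1.54 in untreated wild type (exact permutation p = 0.0286, the smallest possible), and 4.9 ± 1.96 and 5.18 ± 2.91 in challenged mutants and wild type (exact permutation p = 0.914). The score thus rose with challenge in wild type and in mutants (exact permutation p = 0.0286, the smallest possible, in each), and the genotypes differed in untreated lungs. No explanation of this was tested.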
